A study of Mus musculus with 30 samples.

How the data were processed

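Expression was measured in forebrain tissue of 30 male C57BL mice, 10 treated with clozapine, 10 with haloperidol and 10 untreated, each on its own Affymetrix MOE430A array with no pooling, per the series design text. Per the labels' protocols, mice were housed singly on a 12-h light and dark cycle, the drugs were put in the drinking water for 12 weeks at the highest clinical dose in man, and brains were frozen after cervical dislocation. Total RNA was extracted with Trizol and biotin-labelled cRNA was made from it, per the labels' protocols. Age is given as 4 weeks in the labels, which cannot be the age of the mice after 12 weeks of treatment. The hemisphere is given as right in the source and description labels and in the design text, and as left in the tissue characteristic; it is called right here. The dose of haloperidol is given in its labels, while the note on the dose in its protocol names clozapine. Samples were assigned to groups by their titles.

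The deposited values are on a log2 scale, 1 value per probe set and array, made with GCRMA per the submitters' processing notes. GCRMA corrects the background using probe sequence, normalizes between arrays and summarises the probes of a set. Its version, the arrays normalized together, the scanner and the scan dates are not given in the sources used here. Values ran from 0.27 to 15.47, and array medians differed between arrays, from 4.63 to 4.88, so distributions were not identical. GCRMA sets probe sets near background to a narrow range of low values, which shrinks differences between weakly expressed genes. The number of mice and the spread between arrays limit the precision. The median SE of a difference was 0.19 on the log2 scale, and the median half-width of its 95% confidence interval was 0.39, or 1.31-fold.

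Of 22690 probe sets, 64 Affymetrix controls were left out and 12944 of the other 22626 had a mean of at least 4 over all arrays. Probe sets were named from the platform annotation supplied with the data, with symbols checked through Entrez identifiers against a RefSeq table: 20380 had 1 gene symbol, 691 several and 1555 none. Probe sets with several symbols were not named. No genome build is named in the sources used here, and no coordinates are given.

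Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), in a single fit of all 30 arrays with a mean per group and 27 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and calls at an adjusted p under 0.05. For 30 gene lists, fixed before the data were examined, camera was run with a preset inter-gene correlation of 0.01 on the probe set of each gene with the highest mean, adjusted over the lists of a comparison; camera with an estimated correlation and fry were run beside it. List symbols that are not current were matched through RefSeq synonyms. Lists with fewer than 5 measured members were not tested, which left 27. The lists covered neurotransmitter receptors, synapses and immediate early genes, lipid, energy and protein metabolism, stress responses, the circadian clock, signalling, neuropeptides, and markers of brain regions and cell types including blood and pituitary; some genes belong to more than 1 list. Named genes followed a rule fixed at the same time: among called probe sets the 12 with the largest change in each direction; where fewer than 5 were called, the smallest p in that direction up to 5, named as not past the threshold; the 4 members with the smallest p from each called list; and 7 receptor genes. Eif3a and the further list members given in a paragraph were named after their values were seen.

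The correlation of the drugs' effects was set beside 100 simulations in which all 3 groups were drawn from the residual arrays, and beside fits with the controls split between the drugs. Permutation tests of single values used 100000 permutations and were two-sided.

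The fit was tested on simulated data for clozapine against control, with 200 of 12944 probe sets changed in each of 20 draws. With residual arrays redrawn whole, 3.9% of 1.25-fold changes, 28.3% of 1.5-fold, 71.2% of 2-fold and 94.8% of 4-fold changes were recovered, with a median of 0 and at most 42 false calls per draw. With independent noise the shares were 5.1%, 31.8%, 72.6% and 95.8%. All sizes of change were mixed in each draw, and the larger ones ease the adjusted threshold for the smaller ones. Recovery of small changes alone, with no large change present, was not simulated and may be lower. A shift of 0.25 added to the astrocyte list, tried with independent noise only, was called by camera in 20 of 20 draws, with 2 calls of other lists in all. Such noise holds no correlation between genes, so these draws do not give camera's rate of false calls on the real arrays.

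Array quality was checked from the 3' and 5' control probe sets, spike-ins, correlations and principal components. Arrays were clustered by average linkage on Pearson correlation over the tested probe sets without using the groups; the clusters were found in the values and are not a batch that the labels name. No array was a copy of another: the closest pair, haloperidol 10 and control 9, had r = 0.994, a median absolute difference of 0.118 and 0% identical values. An array was called outlying when its mean Spearman correlation with its group lay more than 3 scaled MADs below the median of all arrays, which marked 3.

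Alternatives planned before the data were examined were no filter or a minimum of 6, quantile normalization of the values again, median centring, an intensity trend or robust prior, only the compared groups in the fit, arrayWeights, the replicate number as a block, an RNA quality covariate, leaving out the outlying arrays, 1 probe set per gene, and an adjusted p threshold of 0.10. Fits without each outlying array alone, with the array clusters as a block, within clusters, and with residual principal components as covariates were added after seeing the data.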

Results

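Gene expression was measured in the right forebrain of 30 male C57BL mice, a common inbred laboratory strain, with Affymetrix MOE430A arrays, which carry sets of short probes against mouse transcripts. The mice had received clozapine, haloperidol or no drug for 12 weeks, with 10 mice per group and 1 array per mouse. Clozapine is an atypical antipsychotic that binds many receptor types, and haloperidol is a typical antipsychotic that acts mainly as a dopamine D2 receptor antagonist. Both were given in the drinking water, per the labels at 12 mg/kg/day for clozapine and 1.6 mg/kg/day for haloperidol; the haloperidol protocol names clozapine beside this second dose. The study was set up to compare the long-term expression profiles of the drugs in the brain, so each drug was compared with untreated controls and the drugs were compared with each other. Of 22626 probe sets, 12944 had a mean log2 value of at least 4 and were tested. Array medians lay between 4.63 and 4.88 on the log2 scale.

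The arrays fell into clusters that mixed the treatments. The first 3 principal components held 68.7% of the variance. Differences between treatment groups accounted for 4.18% of the first component (permutation test, p = 0.557), 3.34% of the second (p = 0.632) and 4.2% of the third (p = 0.621). Hierarchical clustering without the group labels gave cluster A with 11 arrays, cluster B with 8, cluster C with 7, and 4 arrays on their own. Cluster A held 3 control, 3 clozapine and 5 haloperidol arrays, cluster B held 4, 1 and 3, and cluster C held 2, 5 and 0 (Fisher's exact test over the 3 clusters, p = 0.109). By replicate number, cluster A held only arrays numbered 1 to 6 and none of those numbered 7 to 10, while B and C held both. The 3' minus 5' difference of the Gapdh and Actb control probe sets, a sign of RNA quality, was 0.64 ± 0.11 (SD, n = 11) on the log2 scale in A, 0.60 ± 0.15 (n = 8) in B and 1.06 ± 0.22 (n = 7) in C. Haloperidol 2, haloperidol 7 and control 1 correlated less with their groups than the other arrays did. Control 1 and haloperidol 7 also had the widest 3' minus 5' differences, 4.09 and 2.45.

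**Figure D1:**
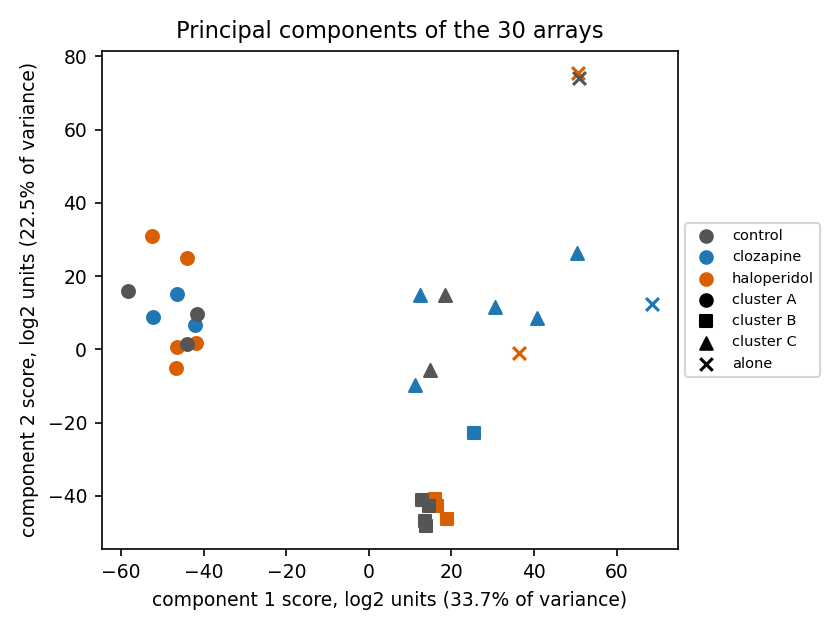
Scores of the 30 arrays on the first principal component (33.7% of variance, x axis) and the second (22.5%, y axis) in log2 units; colours mark the treatment groups and shapes the array clusters, with crosses for arrays on their own. Arrays of the 3 groups lie together within cluster A, while cluster C holds no haloperidol array. Cluster B holds 1 clozapine array, at 25.6 and -22.9. Its control and haloperidol arrays lie apart from that one, at 12.9 to 18.9 and -48.3 to -41.

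The comparison of clozapine with control asked which transcripts differ in the forebrain after 12 weeks of the drug. The smallest p-value among transcripts with a higher mean in clozapine-treated mice was that of Dbp, a transcription factor of the circadian clock's output. Its log2 value was 10.03 ± 0.25 (SD, n = 10) in clozapine against 9.29 ± 0.45 in control, a difference of 0.74 (SE 0.18) or 1.67-fold, and 10 of 10 clozapine arrays lay above the control mean. Mt2, a metal-binding metallothionein, had 10.21 ± 0.22 against 9.82 ± 0.26, a difference of 0.39 (SE 0.12). Among lower transcripts, Sppl2a, an intramembrane protease, had 5.16 ± 0.15 against 5.69 ± 0.44, a difference of -0.53 (SE 0.14), with 10 of 10 clozapine arrays below the control mean. Its difference within clusters was -0.17 in A, -0.0018 in C and -1.09 in B, which holds 1 clozapine array. None of these transcripts passed the correction: limma called 0 of 12944 probe sets at the adjusted p threshold of 0.05, and the smallest adjusted p was 1.

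Before adjustment, 563 probe sets had p under 0.05, 275 higher and 288 lower in clozapine, where 647 would be expected by chance. The other transcripts with the smallest p among those higher in clozapine were H13, a signal peptide peptidase (difference 0.65, SE 0.16), Mpv17l (0.49, SE 0.14) and Egfl7, a protein secreted by endothelial cells (0.45, SE 0.13). Those lower were Lims1, an adaptor of focal adhesions (-1.06, SE 0.28), Lcorl (-0.97, SE 0.26), Luzp1 (-0.93, SE 0.24) and Mylip, a ubiquitin ligase that acts on the LDL receptor (-0.55, SE 0.15). A second Dbp probe set gave 0.65 (SE 0.23), and the other Luzp1 probe set gave 0.088 (SE 0.082). Other probe sets gave 0.034 to 0.19 for H13, 0.056 to 0.29 for Egfl7, -0.25 and -0.2 for Lims1, and -1.64 and -0.093 for Sppl2a. The Sppl2a probe set at -1.64 had a mean of 3.51, below the filter. With array cluster as a block, a fit chosen after the clusters were seen, Dbp kept a difference of 0.76 (SE 0.16) and Mt2 0.39 (SE 0.10), whereas Luzp1 had -0.41 (SE 0.14), Lims1 -0.46 (SE 0.21), Lcorl -0.57 (SE 0.21) and Sppl2a -0.33 (SE 0.13). In the same fit H13 had 0.42 (SE 0.15), Mpv17l 0.35 (SE 0.11), Egfl7 0.39 (SE 0.13) and Mylip -0.44 (SE 0.15). That fit called 0 probe sets and put 897 at unadjusted p under 0.05. Limma with arrayWeights, which gives each array a weight from its spread, called 1731 probe sets, 863 higher and 868 lower. It weighted controls 7 to 10, all of cluster B, at 3.44 or more, and it called 0 when the cluster block was added. Without the 3 outlying arrays 0 were called and 1470 had unadjusted p under 0.05, and without control 1 alone 0 and 868.

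**Figure D2:**
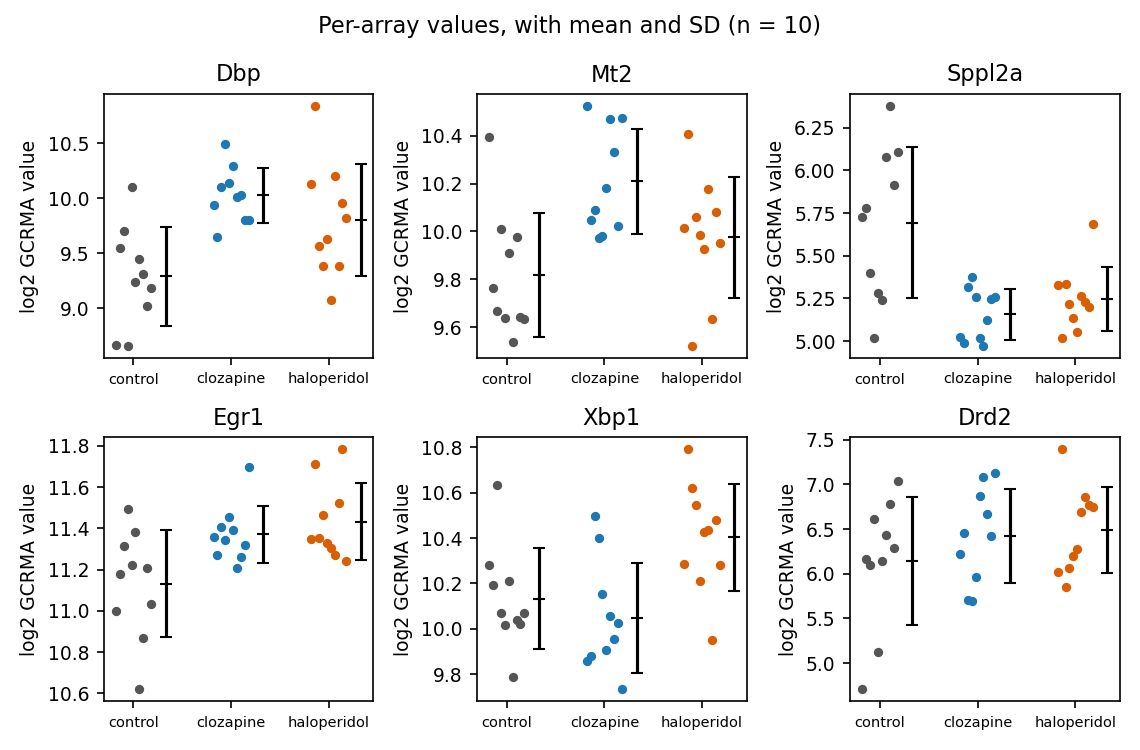
Log2 GCRMA values (y axis) of Dbp, Mt2, Sppl2a, Egr1, Xbp1 and Drd2 in each array, by treatment group (x axis); each point is 1 mouse, and the bars give the mean and SD of the 10 mice. Dbp means were 9.29 in control, 10.03 in clozapine and 9.80 in haloperidol, and Drd2 means were 6.14, 6.42 and 6.49.

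Of the gene lists fixed before the data were examined, 27 had enough measured members to be tested, and 0 were called in clozapine against control by camera, with 1 called by fry. The circadian clock list had the largest median difference, 0.22 on the log2 scale, with 11 of its 17 measured members higher (camera adjusted p = 0.0976; adjusted p = 0.177 with an estimated correlation). Fry, which tests whether a list's genes move on balance to one side, called that list (adjusted p = 0.0234). Its members included Per1 with a difference of 0.67 (SE 0.30), Nr1d1 with 0.66 (SE 0.34) and Arntl, a core activator of the clock, with -0.42 (SE 0.20). Other members of the list were Npas2 with 0.54, Cry1 with 0.31, Nfil3 with -0.255 and Hlf with -0.17. With the cluster block camera called the circadian list upward (adjusted p = 0.0116; adjusted p = 0.293 with an estimated correlation) and the immediate early list downward (adjusted p = 0.0212; adjusted p = 0.807 with an estimated correlation). Fry with the block did not call the circadian list (adjusted p = 0.0621). The genes of GABA synthesis, transport and receptors had a median of -0.16, with 7 of 11 lower (adjusted p = 0.0976), and -0.081 with the cluster block (adjusted p = 0.207). Camera called it downward with no filter on low values (adjusted p = 0.0141; adjusted p = 0.158 with an estimated correlation) and without control 1 (adjusted p = 0.0428; adjusted p = 0.632 with an estimated correlation). The call with no filter also took in the glutamate (adjusted p = 0.0247; adjusted p = 0.158 with an estimated correlation) and microglia lists (adjusted p = 0.0211; adjusted p = 0.172 with an estimated correlation), downward. Gad2, a GABA-synthesising enzyme, had -1.34 (SE 0.51), and -0.47 with the block, while Gad1 had 0.0077 (SE 0.16). Adjusted over the list alone, 2 members passed, Dbp in the circadian list and Mt2 in the antioxidant list, against 0 over all probe sets.

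The other lists had adjusted p of 0.498 or more in this comparison. With all probe sets of the genes camera called the ribosomal list upward (adjusted p = 0.0155; adjusted p = 0.837 with an estimated correlation) and the Akt, GSK3 and Wnt list downward (adjusted p = 0.0323; adjusted p = 0.593 with an estimated correlation). Median log2 differences were 0.024 for dopamine receptors and handling, 0.028 for glutamate receptors and transporters, -0.0048 for synaptic vesicle genes and -0.033 for immediate early genes. They were 0.065 for cholesterol biosynthesis, 0.080 for fatty acid synthesis, -0.0030 for the mitochondrial respiratory chain, 0.063 for cytosolic ribosomal proteins and -0.0066 for proteasome subunits. Stress-related lists had 0.042 for antioxidant defence, 0.077 for cytosolic heat shock proteins, -0.026 for endoplasmic reticulum chaperones and -0.0093 for glucocorticoid-responsive genes, and the Akt, GSK3 and Wnt list had 0.020. Neuronal markers had 0.062 for striatal medium spiny neurons, -0.023 for cortical projection neurons, -0.043 for thalamic and midbrain neurons, 0.14 for cerebellar neurons, -0.011 for the olfactory bulb and 0.050 for neuropeptides. Non-neuronal markers had -0.071 for oligodendrocytes, -0.032 for astrocytes, -0.015 for microglia, 0.089 for endothelial cells and pericytes and 0.086 for choroid plexus and ependyma. For the striatal, glutamate, Akt and endothelial lists the median was positive and camera's direction was down, and for the glucocorticoid and respiratory chain lists the reverse held.

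The comparison of haloperidol with control asked the same of the second drug. By camera with a preset correlation, 3 lists shifted upward in haloperidol-treated mice. The immediate early genes, which neurons induce when active, had a median difference of 0.21 with 12 of 16 higher (adjusted p = 0.00586; adjusted p = 0.654 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.085 with 24 of 29 higher (adjusted p = 0.00269; adjusted p = 0.654 with an estimated correlation). The circadian clock list had a median of 0.17 with 11 of 17 higher (adjusted p = 0.0411; adjusted p = 0.135 with an estimated correlation).

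No single member of these lists passed the test, over all probe sets or adjusted over the list alone. Among the immediate early genes Egr1 had 11.43 ± 0.19 (SD, n = 10) in haloperidol against 11.13 ± 0.26 in control, a difference of 0.30 (SE 0.10). Nr4a1 had a difference of 0.52 (SE 0.28), Egr2 0.45 (SE 0.31) and Nr4a2 0.23 (SE 0.16), although another Nr4a2 probe set gave -0.11 (SE 0.18). Ribosomal proteins had Rps14 at 0.41 (SE 0.22), Rpl35 at 0.30 (SE 0.16), Rps24 at 0.25 (SE 0.12) and Rps28 at 0.23 (SE 0.12); other probe sets gave 0.015 to 0.17 for Rps24 and -0.023 to 0.2 for Rpl35. With the block Rps14 had 0.16, Rpl35 0.086, Rps28 0.13, Egr2 0.28 and Nr4a2 0.4. Rps14 was at 9.53 in control 1 and at 11.62 or more in every other control; without control 1 its difference was 0.17 (SE 0.13), and that of Nr4a1 0.32 (SE 0.25). Cry2 had 0.16 (SE 0.12) without haloperidol 2. In the circadian list Per2 had 0.56 (SE 0.25), Dbp 0.51 (SE 0.18), Cry2 0.26 (SE 0.14) and Arntl -0.38 (SE 0.20); without the 3 outlying arrays Dbp had 0.26, Cry2 0.12, Arntl -0.24, Rpl35 0.14, Rps14 0.24 and Nr4a2 0.39. With the cluster block 0 lists were called (smallest adjusted p = 0.127), the medians were -0.014 for the ribosomal, 0.056 for the circadian and 0.11 for the immediate early list, and the Dbp difference was 0.15 (SE 0.16). The immediate early call was also lost without control 1 (median 0.077, adjusted p = 0.174) and with the RNA quality covariate (median 0.090, adjusted p = 0.213). The ribosomal call was lost with quantile normalization (median 0.077, adjusted p = 0.0918) and with no filter on low values (median 0.089, adjusted p = 0.0647). Without haloperidol 2 the immediate early list had a median of 0.12 (adjusted p = 0.00699; adjusted p = 0.656 with an estimated correlation) and the ribosomal list 0.054 (adjusted p = 0.0157; adjusted p = 0.784 with an estimated correlation), and without the 3 outlying arrays the immediate early median was 0.14. The circadian call was lost under every alternative tried other than leaving out haloperidol 2 (adjusted p = 0.019; adjusted p = 0.0797 with an estimated correlation), with adjusted p = 0.0562 without control 1 (median 0.18) and adjusted p = 0.162 without haloperidol 7 (median 0.16). Its median was 0.12 without the 3 outlying arrays and 0.21 with quantile normalization.

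Limma called 0 of 12944 probe sets in haloperidol against control (smallest adjusted p = 1). At unadjusted p under 0.05 there were 298 probe sets, 108 higher and 190 lower. Those with the smallest p among higher values were a probe set without a single gene symbol (difference 0.55, SE 0.16), Poldip3 (0.50, SE 0.15), Slc9a3r1, a scaffold protein of the cell membrane (0.53, SE 0.16), Pprc1, a transcriptional coactivator (0.57, SE 0.18), and Prr12 (0.41, SE 0.14). Those among lower values were Cox15, an enzyme of heme A synthesis (-0.46, SE 0.13), Strap (-0.43, SE 0.12), the splicing factor Srsf5 (-0.52, SE 0.15), a probe set without a single gene symbol (-0.58, SE 0.17) and Sppl2a (-0.45, SE 0.14). Cox15, Strap, Srsf5 and Sppl2a lay below the control mean in 10 of 10 haloperidol arrays. Other Strap probe sets gave -0.27 (SE 0.2) and 0.13 (SE 0.23). With the cluster block Slc9a3r1 had 0.28 (SE 0.11), Pprc1 0.36 (SE 0.18), Strap -0.26 (SE 0.097) and Srsf5 -0.30 (SE 0.12), and 1 probe set was called, of Eif3a, named here after its values were seen (difference -0.91, SE 0.11, limma adjusted p = 0.00031). The same fit gave 549 probe sets at unadjusted p under 0.05, and leaving out haloperidol 7 gave 749 with 0 called. In the fit without the block the Eif3a difference was -0.82 (SE 0.29).

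The remaining lists had adjusted p of 0.0994 or more. Olfactory bulb markers had a median of 0.17 with 9 of 9 higher (adjusted p = 0.0994), and -0.078 with the cluster block; without haloperidol 7 it was called upward (adjusted p = 0.0348; adjusted p = 0.694 with an estimated correlation). The GABA list had -0.23 with 9 of 11 lower (adjusted p = 0.192), and -0.06 with the block. With no filter on low values the GABA, glutamate and oligodendrocyte lists were called downward (adjusted p = 0.0256 for each; adjusted p = 0.463, 0.402 and 0.463 with an estimated correlation). With all probe sets of the genes the chaperone (adjusted p = 0.0461) and glucocorticoid lists (adjusted p = 0.0484) were called upward (adjusted p = 0.438 for each with an estimated correlation). Medians were -0.063 for the dopamine list, -0.074 for glutamate, -0.065 for synaptic vesicles, -0.033 for cholesterol biosynthesis, -0.085 for fatty acid synthesis, -0.045 for the respiratory chain and 0.0040 for the proteasome. They were 0.065 for endoplasmic reticulum chaperones, -0.0099 for cytosolic heat shock proteins, 0.021 for antioxidant defence, 0.066 for glucocorticoid-responsive genes, -0.10 for Akt, GSK3 and Wnt signalling and -0.077 for neuropeptides. Markers had 0.040 for striatal, -0.027 for cortical, -0.027 for thalamic and midbrain and -0.029 for cerebellar neurons. They had -0.076 for oligodendrocytes, 0.0021 for astrocytes, -0.040 for microglia, -0.12 for endothelial cells and pericytes and -0.054 for choroid plexus and ependyma. For the cholesterol, heat shock, cortical, cerebellar and choroid plexus lists the median was negative and camera's direction was up, and for the astrocyte list the mean was -0.020 with camera's direction up.

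The direct comparison of the drugs addressed the stated purpose of the study. By camera with a preset correlation, 3 lists were lower in clozapine than in haloperidol. The immediate early genes had a median difference of -0.29, with 15 of 16 lower (adjusted p = 0.000147; adjusted p = 0.504 with an estimated correlation). The unfolded protein response and endoplasmic reticulum chaperones had a median of -0.056, with 10 of 17 lower (adjusted p = 0.0263; adjusted p = 0.192 with an estimated correlation). Olfactory bulb markers had a median of -0.15, with 9 of 9 lower (adjusted p = 0.0365; adjusted p = 0.61 with an estimated correlation).

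No member of these lists passed on its own, over all probe sets or adjusted over the list alone. Xbp1, a transcription factor of the unfolded protein response, had 10.05 ± 0.24 (SD, n = 10) in clozapine, 10.40 ± 0.23 in haloperidol and 10.13 ± 0.22 in control, and the difference between the drugs was -0.36 (SE 0.11) with 9 of 10 clozapine arrays below the haloperidol mean. The chaperone Hspa5 had -0.36 (SE 0.21), Pdia3 -0.45 (SE 0.36) and Manf -0.27 (SE 0.14). Among immediate early genes Fos had -0.29 (SE 0.19), Jun -0.32 (SE 0.22), Dusp1 -0.32 (SE 0.22) and Btg2 -0.99 (SE 0.73). The other probe sets of Jun and Btg2 gave -0.018 (SE 0.16) and -0.082 (SE 0.23). The olfactory bulb markers Meis2, Reln, Islr and Doc2g had -0.24 (SE 0.26), -0.097 (SE 0.11), -0.23 (SE 0.27) and -0.35 (SE 0.46). Leaving out haloperidol 2 gave -0.043 (SE 0.4) for Doc2g and -0.045 (SE 0.24) for Islr, with an olfactory median of -0.045, and the olfactory call was lost (adjusted p = 0.309). Leaving out haloperidol 7 gave -0.55 (SE 0.45) for Doc2g and -0.055 for Reln, with an olfactory median of -0.30 and the list called (adjusted p = 0.029; adjusted p = 0.698 with an estimated correlation). Without haloperidol 2 Pdia3 had -0.69 and Manf -0.17. With the cluster block the immediate early list (adjusted p = 1.22e-05) and the chaperone list (adjusted p = 0.0407) were called by camera, the latter with a median of -0.10, and the olfactory list was not (adjusted p = 0.265). With the block and an estimated correlation both lists had adjusted p = 0.556, and fry gave adjusted p = 0.607 and 0.713. With the block Meis2 had -0.12, Doc2g -0.12, Islr -0.37, Dusp1 -0.52, Manf -0.047 (SE 0.12), Pdia3 -0.16 (SE 0.13) and Xbp1 -0.22 (SE 0.11). Without the 3 outlying arrays the immediate early list alone was called (adjusted p = 3.58e-06; adjusted p = 0.468 with an estimated correlation), with Btg2 at -1.7, Pdia3 at -0.82, Meis2 at -0.42, Manf at -0.16, Reln at -0.059, Islr at -0.10 and Doc2g at -0.23. With all probe sets of the genes the medians were -0.18 for the immediate early and -0.036 for the chaperone list. The chaperone call was lost without haloperidol 7 (median -0.070, adjusted p = 0.0993). The olfactory call was also lost with the RNA quality covariate (median -0.14, adjusted p = 0.104) and quantile normalization (median -0.19, adjusted p = 0.0502).

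Limma called 0 of 12944 probe sets between the drugs (smallest adjusted p = 0.965), with 406 at unadjusted p under 0.05, 286 higher and 120 lower in clozapine. Higher values with the smallest p were those of the RNA-binding protein Hnrnpdl (difference 0.52, SE 0.15), Spr, the last enzyme of tetrahydrobiopterin synthesis (0.87, SE 0.26), the phospholipid flippase Atp11b (0.66, SE 0.20), Dnajc10, a disulfide reductase of the endoplasmic reticulum (0.46, SE 0.14), and the proteasome subunit Psmd1 (0.37, SE 0.12). Lower values were those of Dennd4b (-0.34, SE 0.092), Luzp1 (-0.81, SE 0.24), a probe set without a single gene symbol (-0.66, SE 0.19), Acat1, a mitochondrial enzyme of ketone body metabolism (-0.41, SE 0.12), and Mylip (-0.47, SE 0.15). Hnrnpdl lay above the haloperidol mean in 10 of 10 clozapine arrays, and its 5 other probe sets gave 0.35 to 0.40. Another Acat1 probe set gave 0.13 (SE 0.13), and the other Luzp1 probe set 0.00033 (SE 0.082). With the cluster block Luzp1 had -0.23 (SE 0.15), Hnrnpdl 0.31 (SE 0.089) and Atp11b 0.39 (SE 0.14); 0 probe sets were called and 763 had unadjusted p under 0.05. Psmd1 had 0.22 and Acat1 -0.27 with the block. Without the 3 outlying arrays 0 were called and 2300 had unadjusted p under 0.05; the counts were 1363 without haloperidol 7 alone and 835 without haloperidol 2 alone, with 0 called.

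The other lists had adjusted p of 0.209 or more between the drugs. Neuropeptides had the highest median, 0.22, with 11 of 12 higher in clozapine (adjusted p = 0.209), and 0.095 with the cluster block (adjusted p = 0.506); without haloperidol 2 the list was called upward (adjusted p = 0.0259; adjusted p = 0.528 with an estimated correlation). With no filter on low values the glucocorticoid list was called downward (adjusted p = 0.0321; adjusted p = 0.281 with an estimated correlation). Medians were 0.088 for dopamine, 0.043 for glutamate, 0.033 for GABA and 0.033 for synaptic vesicle genes. They were 0.077 for cholesterol biosynthesis, 0.099 for fatty acid synthesis, 0.068 for the respiratory chain, -0.029 for ribosomal proteins and -0.027 for the proteasome. They were 0.063 for cytosolic heat shock proteins, 0.014 for antioxidant defence, -0.035 for glucocorticoid-responsive genes, 0.12 for the circadian clock and 0.024 for Akt, GSK3 and Wnt signalling. Markers had -0.032 for striatal, -0.049 for cortical, 0.059 for thalamic and midbrain and 0.15 for cerebellar neurons. They had 0.072 for oligodendrocytes, 0.012 for astrocytes, 0.019 for microglia, 0.060 for endothelial cells and pericytes and 0.0074 for choroid plexus and ependyma. For the GABA, synaptic vesicle, cholesterol, antioxidant, Akt, astrocyte, microglia and choroid plexus lists the median was positive and camera's direction was down.

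**Figure D3:**
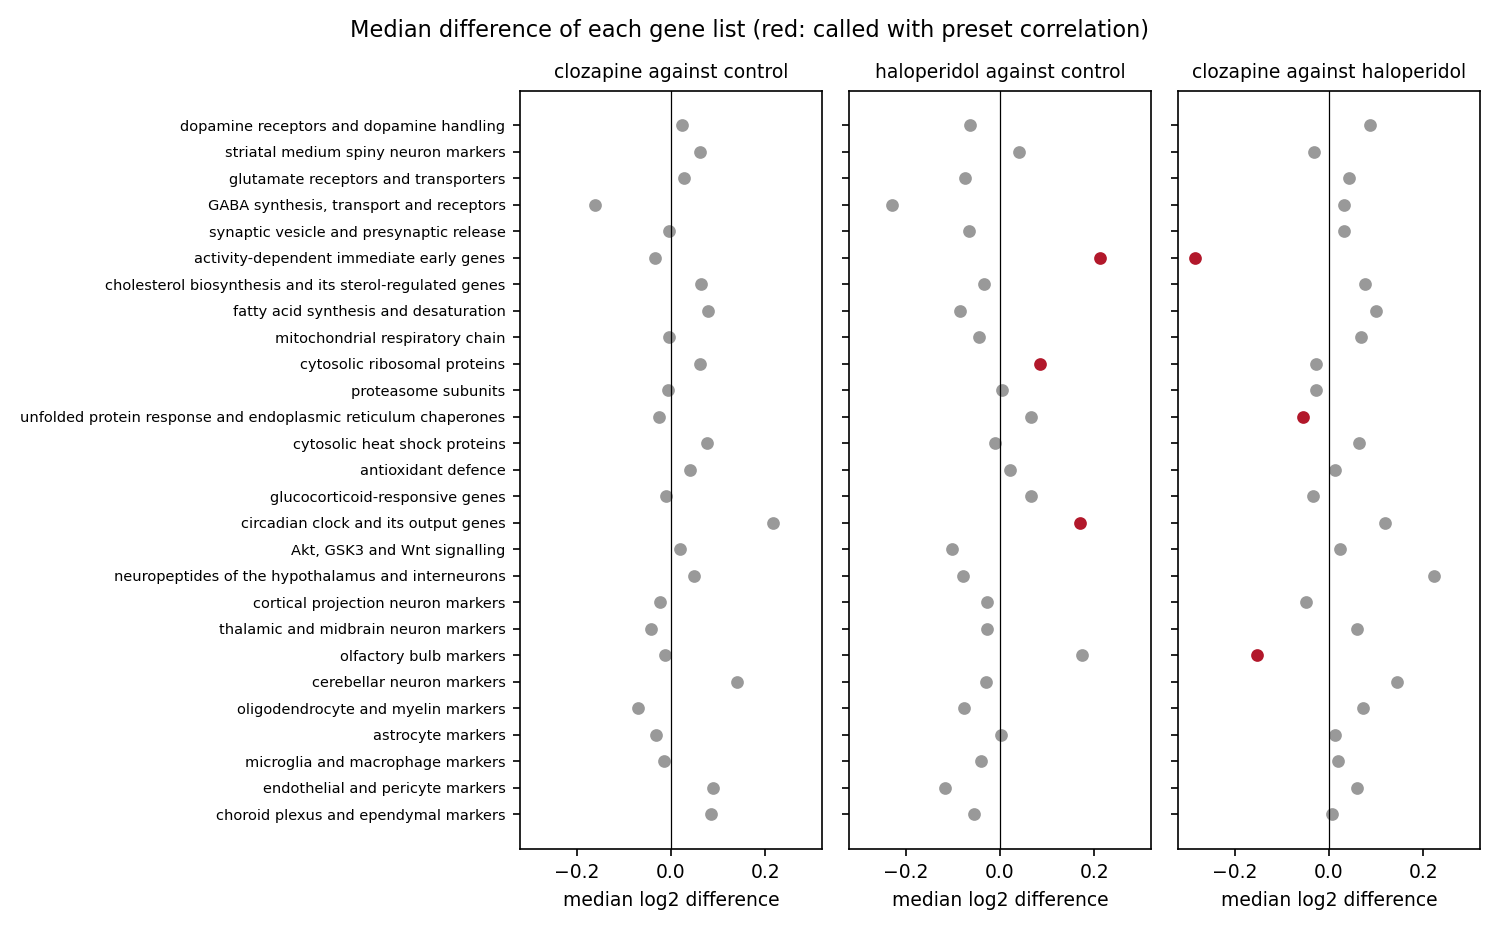
Median log2 difference of the measured members (x axis, log2 units) of each of the 27 tested gene lists (y axis) in the 3 comparisons; each point is 1 list, and red points are lists called by camera with a preset correlation. The called lists lie at 0.085 to 0.21 in haloperidol against control and at -0.29 to -0.056 in clozapine against haloperidol.

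The receptors that the drugs bind were examined whatever their p. Drd2, the dopamine D2 receptor, had 6.14 ± 0.72 (SD, n = 10) in control, 6.42 ± 0.53 in clozapine and 6.49 ± 0.48 in haloperidol, differences of 0.28 and 0.35 (SE 0.25) from control and -0.066 between the drugs. Without control 1 its differences from control were 0.12 and 0.19 (SE 0.23), and without the 3 outlying arrays 0.12 (SE 0.22) and 0.052 (SE 0.23). With the cluster block they were 0.031 (SE 0.15) for clozapine and 0.28 (SE 0.15) for haloperidol, and the difference between the drugs was -0.25 (SE 0.17). The serotonin receptor gene Htr2c had 5.77 ± 1.41, 5.61 ± 1.5 and 5.09 ± 1.63, with differences of -0.16, -0.68 and 0.52 (SE 0.65), and 0.23, -0.1 and 0.33 with the block. The histamine receptor gene Hrh1 had differences of 0.34, 0.43 and -0.088 (SE 0.20), and 0.28, 0.21 and 0.069 with the block; its difference of haloperidol from control was 0.28 (SE 0.17) without haloperidol 7 and 0.20 (SE 0.16) without the 3 outlying arrays. The muscarinic receptor gene Chrm1 was below the filter, with a mean of 3.91 and differences of 0.0028, -0.030 and 0.033 (SE 0.37). None passed the test after adjustment, and the signs of the Drd2, Htr2c and Hrh1 differences turned under some alternatives. Drd1, Htr2a and Adra1a were not analysed here. The list of serotonin, muscarinic, adrenergic and histamine receptors had 4 measured members and was not tested. Besides Htr2c and Hrh1 it held Hrh3, with differences of 0.079, 0.14 and -0.062 (SE 0.21), and Htr1a, with 0.0091, 0.046 and -0.036 (SE 0.17). Blood cell markers had 2 measured members, Bpgm with -0.026, 0.11 and -0.14 (SE 0.18) and Hbb-b2 with 0.19, 0.18 and 0.011 (SE 0.15), and anterior pituitary hormone genes had 0.

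The similarity of the drugs' profiles was measured as the correlation, across probe sets, of the differences from control. Pearson's r was 0.446 and Spearman's rho 0.452, with a covariance of 0.0238; probe sets are not independent replicates. Because both differences share the control arrays, unchanged groups simulated against such controls gave a mean r of 0.479 (range -0.301 to 0.916) and a mean covariance of 0.0368, and 54 of 100 simulations had a covariance as large as that observed. The observed covariance thus differed from the simulated mean by -0.013. With clozapine set against controls 1 to 5 and haloperidol against controls 6 to 10, r was -0.481, and with these controls exchanged it was -0.495. These sets of controls differ in array cluster: controls 7 to 10 are all of cluster B and controls 1 to 5 hold none of it, so these values do not separate drug effects from clusters. Without the 3 outlying arrays r was 0.0553; leaving out haloperidol 2, haloperidol 7 or control 1 alone gave 0.252, 0.2 and 0.589. With 0 calls there was no overlap of called genes; at unadjusted p under 0.05, 29 probe sets were higher and 31 lower with both drugs, against 2.29 and 4.23 for independent lists, which leaves out the shared controls.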

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

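The counts of called probe sets under other splits, the degradation test and the tissue makeup test were chosen after the result was seen. For each named probe set and 5 quality measures, the highest or lowest array of each group of 10 was tested for a wide gap to the nearest of the others (Dixon's test), which 20 of 177 groups met. Chance alone gives about 1 in 20 groups, 8.9 here, and arrays that stand apart in many probe sets meet it repeatedly: control 1 did so 7 times and haloperidol 2 3 times.

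Control 1 was apart from the other controls in Rps14 (9.528, nearest 11.62), Btg2 (3.409, nearest 6.999), Jun (7.392, nearest 8.518), Pdia3 (8.558, nearest 9.887) and Atp11b (9.601, nearest 8.814). It was also apart in the 3' minus 5' difference of control probe sets (4.093, nearest 1.357) and in its mean Spearman correlation with its group (0.953, nearest 0.9678). Haloperidol 2 was apart in Doc2g (9.056, nearest 6.826), Manf (9.732, nearest 9.001) and Pdia3 (8.247, nearest 9.632). Haloperidol 7 was apart in the 3' minus 5' difference (2.454, nearest 1.095) and in Jun (7.357, nearest 8.321). Haloperidol 10 was apart in Dusp1 (7.734, nearest 8.851) and Sppl2a (5.684, nearest 5.336), and haloperidol 4 in Arntl (7.223, nearest 6.225) and Dnajc10 (4.821, nearest 5.56). Single values were those of Luzp1 in clozapine 7 (3.573, nearest 4.809), Egr1 in clozapine 10 (11.7, nearest 11.45), Atp11b in clozapine 3 (8.03, nearest 8.717) and the BioB spike-in in control 5 (10.06, nearest 8.713).

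The first pattern weighed is the separation of the arrays into clusters A, B and C, which were drawn from the same values. RNA degradation as the cause of the separation of A and B is argued against by the difference of -0.034 in their mean 3' minus 5' values, below the SD within each cluster, while A and C differ by 0.424, more than either SD, so degradation may contribute there. Other quality measures did differ between A and B, the 18S rRNA control (11.34 ± 1.97 against 5.02 ± 1.56, SD), Actb 3' (14.68 ± 0.086 against 14.04 ± 0.16) and BioB (8.66 ± 0.79 against 7.57 ± 0.21), so a technical difference other than degradation stays open. The clusters also went with the replicate numbers in the titles: all arrays of A were numbered 1 to 6, and none numbered 7 to 10 was in A. The 18S rRNA control was 6.70 or less in arrays numbered 7 to 10. It was 7.72 or more in those numbered 1 to 6 other than control 1 (2.61). The titles do not say what the numbers stand for, and the cause of this order was not tested. Noise or normalization acting on single probe sets stays open: loadings of the first component correlated at 0.371 between 2 probe sets of a gene (2853 genes), above random pairings (at most 0.0304) but between the bounds set for the test; tissue makeup, the biological explanation tested, stays open as well, with the loadings of 10 marker lists at percentile 69 of random lists.

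Other splits of the same 20 arrays into 10 and 10, 100 with the real one, were counted for each comparison. A real count of 0 is reached by every split, so the splits decide nothing for such counts; for the counts above 0 chance cannot be excluded. For clozapine against control, 100 splits called at least the real 0 probe sets (highest other 2), 24 gave at least the real 563 at unadjusted p under 0.05 (highest other 2415) and 100 called at least the real 0 lists (highest other 9). For haloperidol against control these were 100 for the real 0 called (highest other 3058), 76 for the real 298 (highest other 4961) and 26 for the real 3 lists (highest other 7). For clozapine against haloperidol they were 100 for the real 0 called (highest other 0), 53 for the real 406 (highest other 2338) and 10 for the real 3 lists (highest other 5). The split that called 3058 probe sets had 8 arrays of cluster A on one side and 0 on the other, which points to the structure of the samples; with the cluster block the real split called 1 probe set.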

How the results depend on the processing

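Fits with array clusters or residual components, and those leaving out 1 outlying array, as well as estimated correlations beside alternatives, were chosen after the result was seen, and the cause of each change below was not tested unless given. Signal near background is limited by GCRMA, and no dilution of signal was tried. Among single results, alternatives chosen in advance kept direction and side of the threshold in 797 cases, kept direction but lost the call in 25, gained a call in 11 and turned direction in 6. Those added later gave 613, 9, 80 and 28. No named gene was called in the main fit, so most cases that kept their side were genes that stayed uncalled. Only the called lists, 3 in haloperidol against control and 3 in clozapine against haloperidol, could lose a call. For lists the direction is camera's. The ribosomal median in haloperidol against control turned from 0.085 to -0.014 with the cluster block while camera's direction stayed up. Called probe sets stayed at 0 in all 3 comparisons under every alternative chosen in advance other than arrayWeights, which called 1731 in clozapine against control.

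With the cluster block 1 was called in haloperidol against control, and 5 with arrayWeights and the cluster block. Within cluster B, with 1 clozapine array assumed to vary like the other groups, 405 were called in clozapine against control and 184 in clozapine against haloperidol. With 1, 2, 3 and 4 residual components clozapine against control had 1, 125, 505 and 931, clozapine against haloperidol 12, 49, 787 and 1120, and haloperidol against control 161 and 296 with 3 and 4; components fitted to the same values lower the spread by construction.

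Lists called in clozapine against control numbered 1 with fry, 2 with all probe sets of the genes, 3 with no filter, 2 with the cluster block and 0 to 1 leaving out 1 outlying array, against 0. In haloperidol against control they numbered 0 with an estimated correlation, 0 with fry, 1 with the RNA quality covariate, 1 with quantile normalization and 0 with the cluster block, against 3, and 1 to 3 leaving out 1 outlying array; with no filter and with all probe sets they were 4, not the same lists. In clozapine against haloperidol they numbered 0 with an estimated correlation, 0 with fry and 1 without outlying arrays, against 3. Among list calls under any setting, the smallest adjusted p with an estimated correlation under that setting was 0.0797. The median of 3, 10 and 7 of 27 lists turned sign with the cluster block in clozapine against control, haloperidol against control and clozapine against haloperidol. The correlation of the drugs' effects was 0.0553 without outlying arrays and -0.481 and -0.495 with split controls, of which 1 set holds the 4 controls of cluster B and the other 0.

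Directions turned for these genes, none of them called. In clozapine against control: within cluster A, Lims1 0.111, Drd2 -0.00645 and Hrh1 -0.174; within B, Drd2 -0.412 and Htr2c 0.0403; within C, Htr2c 0.541; with the cluster block, Htr2c 0.23; with arrayWeights, Drd2 -0.0404; with arrayWeights and the cluster block, Drd2 -0.0754 and Htr2c 0.269. In haloperidol against control: within A, Egr2 -0.0303, Rpl35 -0.0317, Dbp -0.23 and Hrh1 -0.00545; within B, Rps28 -0.00386 and Htr2c 0.0857; with arrayWeights, Drd2 -0.108. In clozapine against haloperidol: within A, Meis2 0.00125 and Doc2g 0.0947; within B, Hnrnpdl -0.0232, Meis2 0.197, Reln 0.153, Islr 0.0371, Doc2g 0.155, Htr2c -0.0454 and Hrh1 0.0228; with arrayWeights, Drd2 0.0677 and Hrh1 0.194; without outlying arrays, Drd2 0.0724 and Hrh1 0.178; with the cluster block, Hrh1 0.0691, and with arrayWeights added 0.104. Leaving out 1 outlying array gave -0.0656 to 0.035 for Drd2 and -0.088 to 0.0615 for Hrh1 in that comparison.

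With the replicate block 0, 0 and 0 probe sets were called in clozapine against control, haloperidol against control and clozapine against haloperidol, with 846, 540 and 642 at unadjusted p under 0.05, and 0, 2 and 3 lists; the correlation was 0.446. Without the block the unadjusted counts were 563, 298 and 406. Same-numbered arrays were not closely matched: they correlated at -0.501 to 0.8, with medians of 0.036, 0.17 and 0.25. The correlation was over 0.1 in 5, 5 and 7 of 10 pairs, and an array correlated best with its own number in 4, 2 and 4 of 20 cases. The number is still not unrelated to the values, since no array numbered 7 to 10 was in cluster A.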

Other observations

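The clock phase test, both tests of the output genes, the array cluster fits and the neuropeptide and cerebellar examples were chosen after the result was seen. Between the drugs, 11 of 12 neuropeptide genes had higher means in clozapine than in haloperidol, with a median log2 difference of 0.22 (camera adjusted p = 0.209). Without haloperidol 2 the list was called (adjusted p = 0.0259; adjusted p = 0.528 with an estimated correlation), and with the cluster block the median was 0.095 (adjusted p = 0.506). Sst, which encodes somatostatin, had a difference of 0.34 (SE 0.14), Avp, which encodes vasopressin, 0.49 (SE 0.35), Vip 0.31 (SE 0.36) and Npy 0.25 (SE 0.22); with the block these were 0.33, 0.41, 0.029 and 0.14. Against control Sst had 0.034 in clozapine and -0.31 in haloperidol. Of the cerebellar neuron markers, measured here in forebrain tissue, 7 of 8 had higher means in clozapine than in haloperidol, with a median of 0.15 (camera adjusted p = 0.294), among them Pcp4, a calmodulin regulator, with 0.33 (SE 0.14). None of these genes passed the test on its own.

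Eif3a, a translation initiation factor subunit, was the probe set called in haloperidol against control with the cluster block. That probe set had means of 4.78 in haloperidol and 5.55 in control in cluster A, and 5.10 and 6.02 in cluster B. The other 3 Eif3a probe sets had cluster-block differences of -0.070, 0.20 and -0.073, at mean log2 values of 9.28, 8.14 and 10, against a mean of 4.89 for the called probe set. Of 100 relabellings within clusters, the real one included, 1 called as many as the real 1 (highest other 0), the lowest share that this test can give. The fit was chosen after the clusters were seen, and relabelling was run only for the comparison in which it had made a call. The count therefore does not exclude chance.

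The second pattern weighed is the 1731 probe sets called with arrayWeights in clozapine against control. Chance cannot be excluded: with weights estimated anew, 16 of 100 splits called as many (real 1731, highest other 5712). Uneven weight on the closely similar controls of cluster B is a candidate explanation, since arrayWeights with the cluster block called 0. An effect of clozapine stays open and was not told apart from it.

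The third pattern weighed is the higher level of circadian output genes in clozapine, a hypothesis, since the gene sets were written when the shift of the whole list and the values of Dbp, Per1 and Per2 were known. The mean of 8 output genes was 8.24 ± 0.12 (SD, n = 10) in clozapine, 7.90 ± 0.15 in control and 8.10 ± 0.28 in haloperidol; the difference of clozapine from control was 0.34, with 8 of 10 clozapine arrays above every control, and a test of this difference on genes so chosen is void. Array clusters as the whole cause are argued against by the difference within clusters, 0.37 against 0.34 for the output genes and 0.39 against 0.32 for the output minus antiphase score; permutation within clusters gave p = 0.00055 and p = 0.0111, which bear on clusters alone and not on whether the pattern holds, as the genes are the same. Few distinct relabellings exist within clusters, of which B holds 1 clozapine array, so the first p lies near the lowest that this permutation can give. A shift of clock phase or of the time of sacrifice may also move these genes and stays open. The time of sacrifice is not given in the sources used here. A permutation test of the score gave p = 0.105, and the mean of the 5 antiphase genes differed by 0.024. Those genes moved both ways in clozapine, with Arntl at -0.42, Nfil3 at -0.255, Clock at -0.047, Npas2 at 0.54 and Cry1 at 0.31. Among the output genes Hlf was lower, at -0.17. The score also varied among untreated mice, from 0.74 to 0.90 in controls 1 to 3 and from 1.88 to 2.11 in controls 7 to 10. It was 0.50 in haloperidol 4 and 2.59 in haloperidol 10, but 2.19 in clozapine 1 and 1.88 in clozapine 10. Controls 7 to 10 are all of cluster B, and a trend with mouse number was not tested. Chance choice of genes stays open too. The 5 output genes other than Dbp, Per1 and Per2 had a difference of 0.19. Relative to its standard error, a difference as large was reached by 0.95% of random lists. That test is void because these genes' values were known when it was chosen.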
